A study of Homo sapiens with 4 samples.

How the data were processed

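Messenger RNA of PLC8024, a human liver cancer cell line, was sequenced in 2 control and 2 drug-treated libraries. Per the labels, RNA was extracted with trizol, and libraries followed the Illumina TruSeq stranded mRNA guide. Reads were demultiplexed with bcl2fastq and the genome build was hg38, per the submitters' processing notes, which give no versions. The aligner, counter, annotation and test tool are not given in the sources used here. The labels name neither drug, dose nor duration, and do not say whether libraries came from separate cultures.

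One table of 26603 genes was used. The 4 per-library columns are deposited FPKM values, identified from the values because the header names no unit. With GENCODE 29 exon lengths the median ratio of implied to annotated length was 1.00, and 57.4% of genes lay within 1%. The group columns are deposited mean normalized read counts, a signal that the authors made by dividing reads by a size factor per library. The log2 fold changes of drug over control are the authors' own comparison, per the file headers. The deposited p-value and adjusted p-value columns are the authors' own, and the latter equals the Benjamini-Hochberg adjustment over the 26603 genes to within 0.585%. No per-sample column was left unused. Columns were matched to samples by name and number. All genes had reads in at least 1 control library (0 were at 0 in both), while 2073 were at 0 in both drug libraries, so genes expressed with drug alone were not analysed here. Of the gene identifiers, 25091 were in GENCODE 29 and 1512 were not.

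Whole reads per library were recovered from FPKM and group means together, with 100% of values within 0.1 read of a whole number. Totals were 28526098 and 38611635 in control and 40279560 and 38685856 in drug libraries, with 23466, 24464, 22854 and 23137 genes having a read. On simulated data, read recovery was exact for 100% of values. DESeq2 1.42.0 on the recovered reads gave fold changes within 0.0001 of the authors' log2 values. Replicates correlated across genes at 0.993 (control) and 0.992 (drug), against 0.986 to 0.987 between groups. Genes are not independent replicates, and the replicate number of a library was tested as a block only as an alternative.

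Choices were fixed before the data were examined: the comparison, tests, 47 gene lists, naming rule and a first set of alternatives. They assumed a count table, so the design's own fallback for normalized values was used. Genes with a mean of at least 1 FPKM in a group were tested with limma 3.58.1 (trend) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera sets list members against the other tested genes, so its calls as higher or lower are relative to those genes, while fry tests the list itself. Of 948 list genes 881 were in the table. Alternatives were pseudocounts of 0.1 and 0.01, no filter, a replicate block, and each library left out. Those added after the data were seen were TMM-scaled FPKM, edgeR 4.0.16, DESeq2 and limma-voom on recovered reads, tests against a fold of 1.5, a spline correction for GC content, exon length and abundance, removal of genes discordant between replicates, and 1 list without FBL.

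Named genes followed a rule. They passed limma, had a mean of at least 2 FPKM and had both drug libraries on the same side of both controls. The 12 largest rises and 12 largest falls were taken, leaving out pseudogenes and antisense genes, with up to 4 members per list in its own direction and 2 in the other. ALB, AFP, CDKN1A, MYC, MKI67, DDIT3 and HMOX1 were added as references. A further 37 genes lie outside the rule and were named after their values were seen: members of small counts in a list, and members of 3 lists written after the values were seen. Some genes that the rule picks are not reported here. On simulated data for this comparison (10760 genes, 200 changed), limma recovered 14% of genes changed 1.25-fold, 75% at 1.5-fold, 89.6% at 2-fold and 98% at 4-fold. Of 149 genes called there 14 were unchanged, and 0 of 41 lists were called by camera. Genes were simulated independently of each other, so this cannot show how camera behaves when list members vary together. In the data the estimated correlation ran from -0.101 (gluconeogenesis and glycogen) to 0.892 (mitochondrial genome) over the fixed lists tested. Groups of 2 are too small for a test of outlying samples. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.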

Results

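Gene expression was measured by RNA sequencing in PLC8024, a human liver cancer cell line, in 2 libraries labelled control and 2 labelled drug. The labels name neither the drug nor its dose or duration. Recovered gene reads totalled 28526098 and 38611635 in control libraries 1 and 2, and 40279560 and 38685856 in drug libraries 1 and 2. Values are fragment counts scaled for exon length and library total (FPKM), and groups are given as mean ± SD with n = 2 libraries each. The single comparison asks which transcripts differ between drug-treated and control cells. Log2 fold changes are on the FPKM + 1 scale, which understates the change of genes with low values, while values given as -fold are ratios of mean FPKM. Labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples.

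With drug, PLC8024 cells had higher levels of FBL, CYP1A1, GSTP1 and LGR5 and lower levels of HAL, SLC12A3, SDS and SCD. By camera with its preset correlation, lists of mitotic, cytoskeletal and heat shock genes were higher by small amounts, and lists of hypoxia, glycolysis, lipid synthesis, and complement and coagulation genes were lower. None of them passed with an estimated correlation (lowest adjusted p of the 42 fixed lists tested 0.362). That test has 2 residual degrees of freedom here, so a lost call alone does not show that list members vary together. The estimated correlation was -0.0135 for mitosis, below the preset 0.01, but 0.395 for hypoxia and 0.451 for glycolysis. FBL, which encodes the methyltransferase of box C/D small nucleolar particles, rose 13.96-fold. CYP1A1, a cytochrome P450 whose transcription the aryl hydrocarbon receptor drives, rose 9.31-fold. FBL had 150 and 307 reads in the control libraries, and whether reads were placed on other copies of its sequence was not tested. Of 11227 genes tested with limma, 873 rose and 676 fell at an adjusted p under 0.05, so 56.4% of the 1549 calls were higher. Most changes were modest. The median absolute log2 fold change of called genes was 0.28, and 37 rose and 73 fell by more than 2-fold. Protein-coding genes made up 823 of the risers and 583 of the fallers, while of 602 pseudogenes tested 18 rose and 49 fell. The direction split depends on the scaling: with TMM-scaled FPKM 554 genes rose and 779 fell (41.6% higher), and with edgeR on recovered reads 1277 rose and 1503 fell (45.9% higher). Of the limma calls, 652 of the 873 and 604 of the 676 also had an adjusted p under 0.05 in the same direction in the authors' deposited table, which has 845 genes up and 1073 down at that threshold and lists 42 as up and 91 as down when a fold over 2 is also asked for. With 1 library left out, limma called 115 to 221 genes as higher and 188 to 274 as lower: 115 and 188 without control 1, 163 and 212 without control 2, 221 and 265 without drug 1, and 178 and 274 without drug 2.

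**Figure D1:**
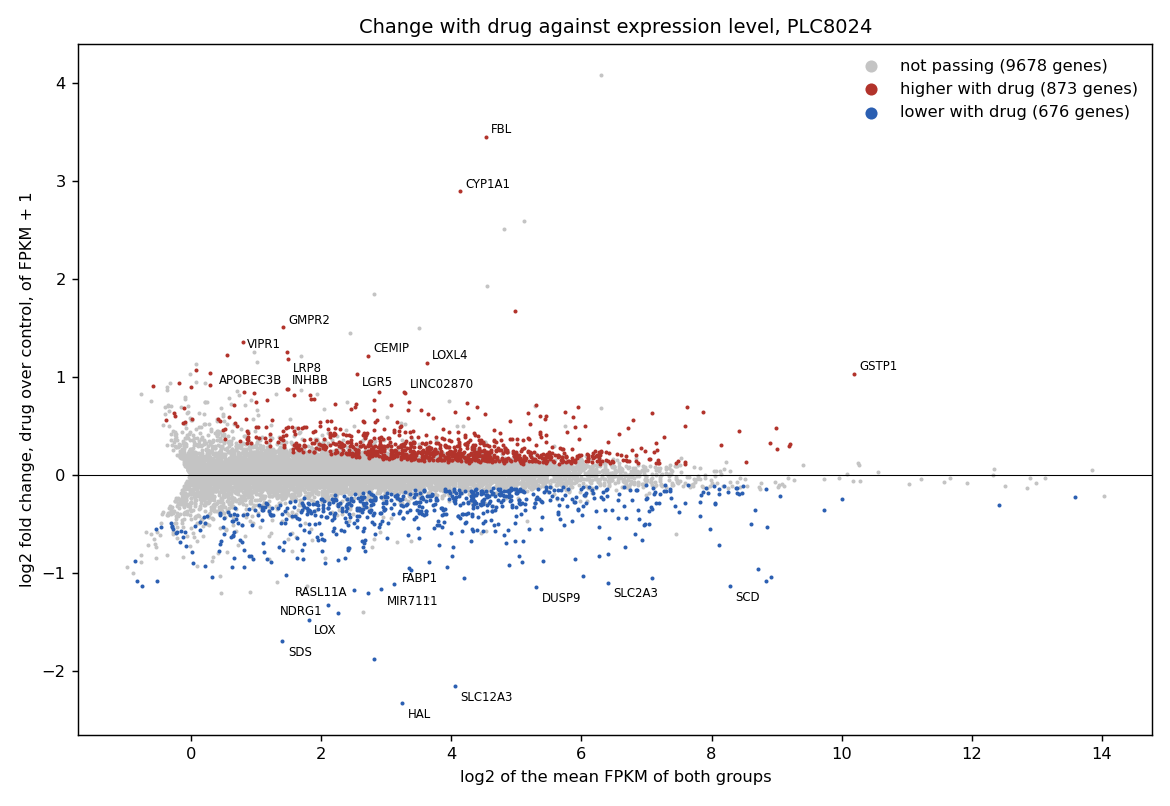
Log2 fold change of FPKM + 1, drug over control, against the log2 mean FPKM for each of the 11227 genes tested, with the 873 higher genes in red, the 676 lower genes in blue and the others in grey. The named genes are 12 of the risers and 11 of the fallers picked by the rule for named genes, which leaves out pseudogenes, antisense genes and genes below a mean of 2 FPKM.

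FBL (ENSG00000105202), the fibrillarin gene, lies on chromosome 19 at 39834458 to 39846414 in GRCh38. It rose from 3.09 ± 0.891 to 43.1 ± 0.242 FPKM (log2 fold change 3.45 ± 0.14 SE, limma adjusted p = 0.00104), and its recovered reads were 150 and 307 in the control libraries and 3700 and 3582 in the drug libraries. With edgeR on recovered reads the adjusted p of FBL was 0.0123. Whether placement of reads on other copies of its sequence in hg38 shaped the FBL values was not tested. CYP1A1 (ENSG00000140465), which encodes an enzyme that oxidises polycyclic hydrocarbons, lies on chromosome 15 at 74719542 to 74725610 in GRCh38. Its level rose from 3.40 ± 0.381 to 31.7 ± 3.21 FPKM (log2 fold change 2.89 ± 0.09 SE, limma adjusted p = 0.000649). GSTP1 (ENSG00000084207), the pi-class glutathione transferase gene, lies on chromosome 11 at 67583595 to 67586656 in GRCh38. It was among the most abundant risers and went from 768 ± 7.93 to 1575 ± 2.13 FPKM (log2 fold change 1.03 ± 0.03 SE, limma adjusted p = 0.000523). LGR5 (ENSG00000139292), a receptor for R-spondins and a Wnt target, lies on chromosome 12 at 71439770 to 71586310 in GRCh38. It rose from 3.49 ± 0.235 to 8.18 ± 0.0480 FPKM (log2 fold change 1.03 ± 0.05 SE, limma adjusted p = 0.00148).

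The vasoactive intestinal peptide receptor gene VIPR1 rose from 1.22 ± 0.0347 to 4.31 ± 0.0720 FPKM, and LRP8, which encodes a reelin and apolipoprotein E receptor, rose from 1.33 ± 0.0382 to 4.28 ± 0.0348 FPKM. CEMIP, whose product takes part in hyaluronan breakdown, rose from 3.58 ± 0.0806 to 9.64 ± 0.898 FPKM, and the lysyl oxidase family member LOXL4 rose from 7.29 ± 0.466 to 17.3 ± 0.0881 FPKM. INHBB, the activin beta B subunit gene, rose from 1.67 ± 0.427 to 3.86 ± 0.163 FPKM. The cytidine deaminase gene APOBEC3B rose from 1.70 ± 0.439 to 3.92 ± 0.105 FPKM and overlaps APOBEC3A on the same strand, so their reads could be shared. The non-coding gene LINC02870 rose from 6.59 ± 0.620 to 12.7 ± 1.98 FPKM, and the guanosine monophosphate reductase gene GMPR2 rose from 0.947 ± 0.657 to 4.39 ± 0.631 FPKM. Limma adjusted p-values of these 8 genes were between 0.00104 and 0.0224. GMPR2 had an edgeR adjusted p of 0.247 and lies within 500 kb of 3 genes whose reads differed more than 4-fold between replicates (EMC9, NOP9 and PCK2). GMPR2 (adjusted p = 0.0892 and 0.0734), APOBEC3B (0.0705 and 0.0676) and INHBB (0.0708 and 0.0653) lost their limma calls without drug 1 or drug 2, and LINC02870 without control 1 (0.0754) or control 2 (0.0587).

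HAL (ENSG00000084110), which encodes histidine ammonia-lyase, the first enzyme of histidine breakdown, lies on chromosome 12 at 95972662 to 95996365 in GRCh38. It fell from 16.5 ± 0.604 to 2.50 ± 0.179 FPKM (log2 fold change -2.33 ± 0.05 SE, limma adjusted p = 0.000523). SLC12A3 (ENSG00000070915), the thiazide-sensitive sodium chloride cotransporter gene, lies on chromosome 16 at 56865207 to 56915850 in GRCh38. It fell from 27.8 ± 0.408 to 5.49 ± 0.336 FPKM (log2 fold change -2.15 ± 0.05 SE, limma adjusted p = 0.000523). SDS, the serine dehydratase gene, fell from 4.58 ± 0.440 to 0.721 ± 0.0623 FPKM, and SCD, which encodes stearoyl-CoA desaturase, fell from 428 ± 23.9 to 194 ± 0.282 FPKM. The liver fatty acid-binding protein gene FABP1 fell from 12.3 ± 0.439 to 5.16 ± 0.332 FPKM. LOX, a hypoxia-induced lysyl oxidase, fell from 5.62 ± 0.969 to 1.37 ± 0.103 FPKM, NDRG1 from 6.57 ± 0.436 to 2.03 ± 0.0803 FPKM and the glucose transporter gene SLC2A3 from 116 ± 4.21 to 53.8 ± 1.07 FPKM. The MAP kinase phosphatase gene DUSP9 fell from 54.9 ± 2.61 to 24.3 ± 0.492 FPKM and RASL11A from 8.26 ± 0.0598 to 3.11 ± 0.300 FPKM. Limma adjusted p-values of these 10 genes were between 0.000523 and 0.00421, and all 10 kept their call with each library left out. The microRNA gene MIR7111 fell from 10.95 ± 3.79 to 4.22 ± 0.120 FPKM on 28 and 23 control reads and 12 and 12 drug reads. It had an edgeR adjusted p of 0.0521 and lost its limma call without drug 1 (adjusted p = 0.103) or drug 2 (0.105).

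**Figure D2:**
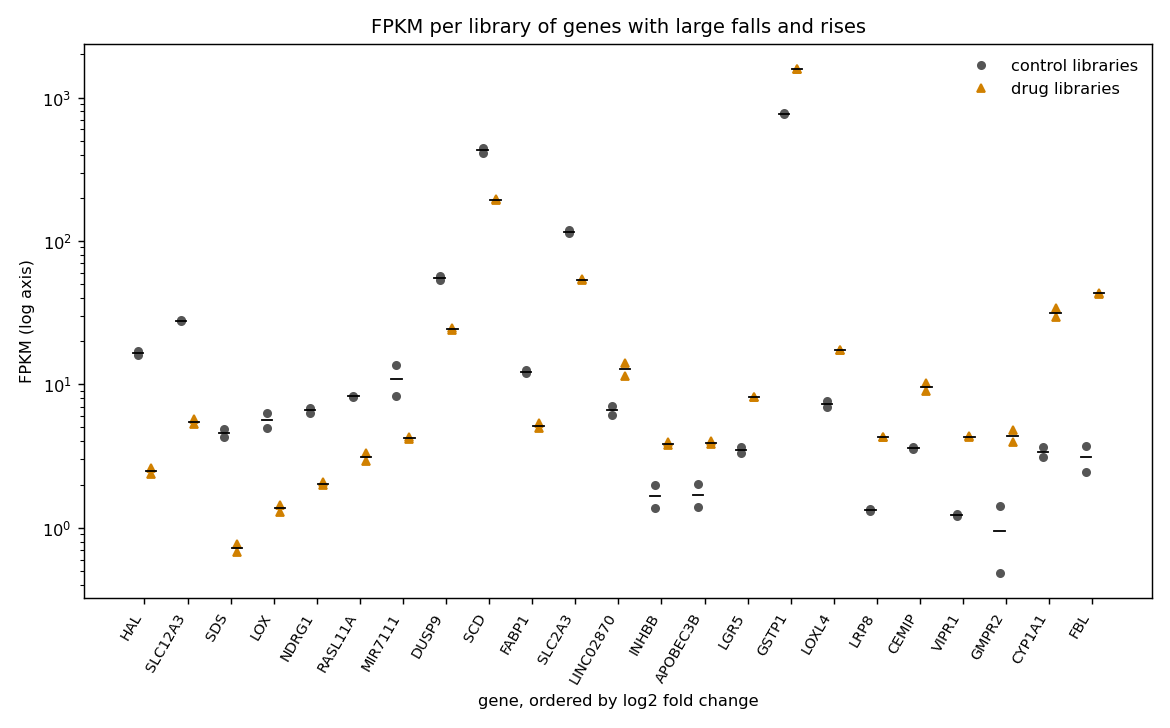
FPKM on a log axis of 11 genes with large falls and 12 with large rises, ordered by log2 fold change, with circles for the 2 control libraries, triangles for the 2 drug libraries and bars for group means. In each of the 23 genes both drug libraries lie on the same side of both control libraries, as the rule for named genes requires. Of all tested genes 63.5% did so.

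Reference genes of liver cancer cells, stress and growth were also read. The albumin gene ALB fell from 3.19 ± 0.0593 to 1.31 ± 0.00616 FPKM, and CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 4.41 ± 0.263 to 2.63 ± 0.254 FPKM. The proliferation marker MKI67 rose from 52.8 ± 0.0214 to 58.6 ± 0.764 FPKM. MYC (20.6 ± 0.630 to 21.6 ± 0.944 FPKM), the stress gene DDIT3 (10.1 ± 1.04 to 10.9 ± 0.119 FPKM) and HMOX1 (59.2 ± 0.484 to 54.6 ± 1.603 FPKM) did not pass the limma test (adjusted p = 0.374, 0.369 and 0.0693). HMOX1 passed as lower with edgeR on recovered reads (adjusted p = 0.00745) and with TMM-scaled FPKM in limma (0.0329). The alpha-fetoprotein gene AFP stayed below the filter, at 0.449 and 0.372 FPKM in control and 0.419 and 0.436 FPKM in drug libraries. MKI67 lost its call whichever library was left out, and CDKN1A lost its call without control 1 or control 2. MKI67 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0538).

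Fixed gene lists were tested next. Of 47 lists, 42 had at least 5 tested members, and by camera with its preset correlation 8 were higher and 17 lower at an adjusted p under 0.05. These calls are relative to the other tested genes, and the median log2 fold change of all tested genes was 0.036. None of these 42 passed camera with an estimated correlation, a test with 2 residual degrees of freedom here, where the lowest adjusted p was 0.362. By fry, 8 lists moved higher and 12 lower on balance, and 41 changed in either direction. Calls of single list members depend on the number of libraries. Of the 202 named genes that passed, 74 did so with each library left out, while 121 lost their call without control 1, 101 without control 2, 92 without drug 1 and 88 without drug 2. Beside each list, calls lost in this way are given for the genes it names. Values in parentheses after a gene run from the control mean to the drug mean, in FPKM with SD.

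**Figure D3:**
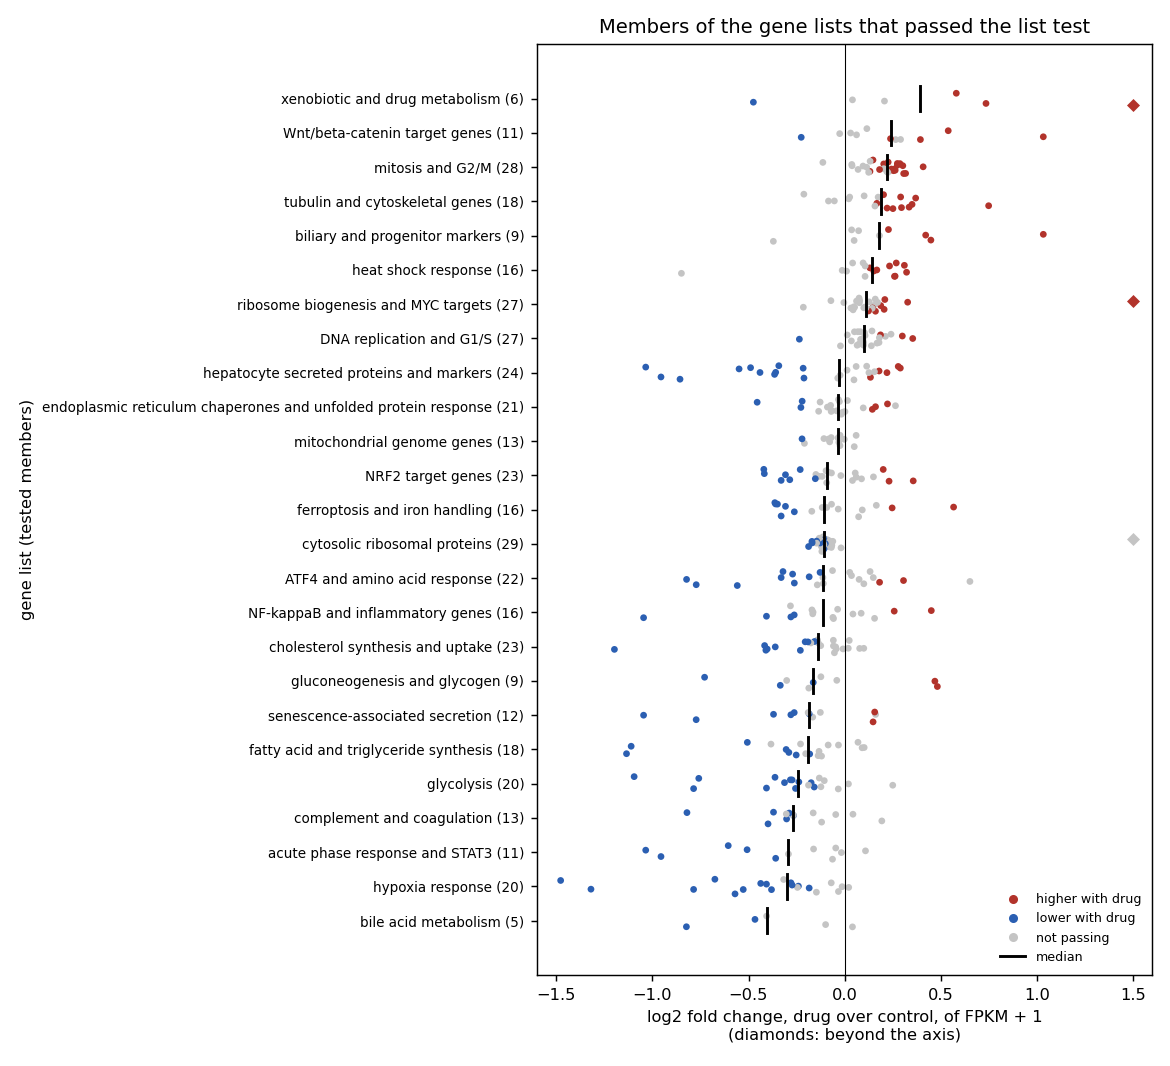
Log2 fold change of FPKM + 1, drug over control, for each tested member of the 25 lists that passed camera, with the number of tested members after each name. Red points rose, blue points fell, grey points did not pass limma, and black bars are list medians; the diamonds stand for CYP1A1 and FBL, which rose, and RPS18, which did not pass, all 3 beyond the axis.

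The hypoxia and glycolysis lists were lower by camera. Among 20 tested hypoxia genes, 13 fell and none rose, among them NDRG1 (6.57 ± 0.436 to 2.03 ± 0.0803 FPKM) and LOX (5.62 ± 0.969 to 1.37 ± 0.103), HILPDA (24.4 ± 1.86 to 14.9 ± 1.21), a lipid droplet protein gene, and PFKFB4 (3.01 ± 0.413 to 1.32 ± 0.00254), a regulator of glycolytic flux. The list had a median log2 fold change of -0.30, and 0 were higher and 15 lower adjusted over the list alone (camera adjusted p = 4.15e-10, adjusted p = 0.362 with an estimated correlation). Of 20 glycolysis genes, 12 fell, with a median of -0.24, and 1 was higher and 13 lower adjusted over the list alone. They included the glucose transporter genes SLC2A3 and SLC2A1 (5.36 ± 0.161 to 3.80 ± 0.309) and the aldolase gene ALDOC (6.95 ± 0.663 to 3.70 ± 0.339) (camera adjusted p = 1.05e-09, adjusted p = 0.362 with an estimated correlation). PFKFB4, SLC2A1 and PDK1 are on both lists, and PFKFB4 and HILPDA overlap UCN2 and HILPDA-AS1 on the same strand. PFKFB4 lost its call without control 1, drug 1 or drug 2, and SLC2A1 lost its call without control 1, control 2 or drug 1. HILPDA and ALDOC lost their calls without control 1.

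The cholesterol and fatty acid synthesis lists were also lower by camera. Of 23 cholesterol genes 9 fell and none rose, and 1 was higher and 12 lower adjusted over the list alone, with a median of -0.14 (camera adjusted p = 7.18e-07, adjusted p = 0.362 with an estimated correlation). Among those that fell were the sterol methyl oxidase gene MSMO1 (36.6 ± 0.332 to 27.2 ± 0.393), the sterol carrier gene STARD4 (8.08 ± 0.163 to 5.83 ± 0.0794) and INSIG1 (16.6 ± 0.224 to 12.4 ± 0.899), whose product retains SREBP in the endoplasmic reticulum. Of 18 fatty acid and triglyceride synthesis genes 7 fell and none rose, and 0 were higher and 10 lower adjusted over the list alone, with a median of -0.19 (camera adjusted p = 5.41e-07, adjusted p = 0.362 with an estimated correlation). Besides SCD and FABP1 they included the transcription factor gene SREBF1 (6.40 ± 0.0634 to 4.21 ± 0.0374) and the desaturase gene FADS1 (22.3 ± 0.190 to 17.9 ± 0.00299). Fatty acid oxidation and PPAR alpha targets went both ways and the list did not pass (camera adjusted p = 0.287). Its 5 risers were CPT1A (37.5 ± 1.58 to 50.1 ± 0.833), which encodes the entry enzyme of mitochondrial fatty acid oxidation, PDK4 (3.78 ± 0.0199 to 5.35 ± 0.265), CREB3L3, SLC25A20 and ACADVL. Its 5 fallers were the lipid droplet gene PLIN2 (44.6 ± 3.41 to 23.6 ± 0.939), ANGPTL4 (5.62 ± 0.445 to 3.45 ± 0.0479), PPARA (3.69 ± 0.131 to 2.97 ± 0.00219), FABP1 and HADHA, and 5 were higher and 6 lower adjusted over the list alone. Of 5 bile acid genes 2 fell, the organic solute transporter gene SLC51B (67.6 ± 2.75 to 48.6 ± 0.880) and the bile acid receptor gene NR1H4 (2.70 ± 0.230 to 1.09 ± 0.0479), and 0 were higher and 3 lower adjusted over the list alone (median -0.41, camera adjusted p = 0.0105, adjusted p = 0.362 with an estimated correlation). That list lost its call without the filter on low values (camera adjusted p = 0.510, median 0.01) and with edgeR on recovered reads (0.0576). CREB3L3, SLC25A20, ACADVL, HADHA and NR1H4 lie outside the rule for named genes and were named after their values were seen. ACADVL, PPARA and HADHA lost their calls whichever library was left out, and PDK4 lost its call without control 1, control 2 or drug 1. INSIG1 lost its call without control 1 or control 2, and STARD4, FADS1, SLC25A20, ANGPTL4 and NR1H4 lost their calls without control 1. ACADVL also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0762).

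Of 24 hepatocyte genes 11 fell, led by the fibrinogen chain genes FGG (648 ± 2.80 to 316 ± 13.3 FPKM) and FGB (552 ± 4.50 to 285 ± 14.9), and ALB and the urea cycle gene CPS1 (301 ± 7.40 to 205 ± 3.65) fell too. The 5 that rose were the transcription factor genes CEBPA (10.1 ± 0.680 to 12.5 ± 0.00823), FOXA2 (13.2 ± 0.351 to 15.5 ± 0.193) and HNF4A (22.4 ± 0.186 to 25.5 ± 0.0976) and the secreted protein genes APOA2 (109 ± 4.65 to 133 ± 6.25) and AMBP (352 ± 4.93 to 386 ± 6.56). In this list 6 were higher and 11 lower adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.00812, adjusted p = 0.362 with an estimated correlation). Among 11 acute phase genes the 5 that fell were FGG, FGB, FGA (950.5 ± 8.92 to 741 ± 29.3) and the orosomucoid genes ORM1 (147 ± 16.8 to 103 ± 7.49) and ORM2 (33.998 ± 2.67 to 22.01 ± 1.94), which are near-identical neighbours and could share reads. None rose, and 0 were higher and 5 lower adjusted over the list alone (median -0.29, camera adjusted p = 9.45e-06, adjusted p = 0.362 with an estimated correlation). Of 13 complement and coagulation genes 6 fell and none rose, with the kininogen gene KNG1 (20.97 ± 0.216 to 11.5 ± 0.677), the factor genes F10 (13.5 ± 0.504 to 9.995 ± 0.153) and F5 (25.98 ± 0.847 to 20.9 ± 0.998) and C5 (7.67 ± 0.0194 to 5.72 ± 0.443) among them. Here 0 were higher and 7 lower adjusted over the list alone (median -0.27, camera adjusted p = 5.34e-06, adjusted p = 0.362 with an estimated correlation). Gluconeogenesis and glycogen genes split: PC (20.7 ± 0.0908 to 12.1 ± 0.507), the pyruvate carboxylase gene, GBE1 (16.04 ± 0.210 to 12.5 ± 0.0526) and PGM1 (23.4 ± 0.203 to 20.8 ± 0.299) fell, and IGFBP1 (426 ± 4.96 to 595 ± 2.02) and the glucose-6-phosphatase gene G6PC1 (12.1 ± 0.405 to 17.2 ± 1.03) rose. Of 9 tested, 2 were higher and 5 lower adjusted over the list alone (median -0.16, camera adjusted p = 0.0225, adjusted p = 0.362 with an estimated correlation), and the list lost its camera call without drug 2 (adjusted p = 0.0634). FOXA2, HNF4A, AMBP and FGA lie outside the rule and were named after their values were seen. FOXA2, HNF4A, AMBP and PGM1 lost their calls whichever library was left out, and CEBPA and ORM1 lost their calls without control 1, drug 1 or drug 2. APOA2 lost its call without control 1, control 2 or drug 1, and F5 and C5 lost their calls without control 1, control 2 or drug 2. FGA and G6PC1 lost their calls without control 1 or control 2, and ORM2, F10 and GBE1 lost their calls without control 1. APOA2 and AMBP also lost their limma calls with TMM-scaled FPKM (adjusted p = 0.0503 and 0.131).

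Of 28 mitosis genes 17 rose and none fell, and 23 were higher and 1 lower adjusted over the list alone, with a median of 0.22 (camera adjusted p = 1.63e-08, adjusted p = 0.362 with an estimated correlation). They included the kinetochore gene NDC80 (17.5 ± 0.153 to 23.6 ± 1.37 FPKM), the kinesin gene KIF20A (15.3 ± 0.365 to 19.3 ± 0.583), the spindle checkpoint gene BUB1B (20.8 ± 0.433 to 25.96 ± 0.861) and the mitotic kinase gene PLK1 (12.6 ± 0.221 to 15.7 ± 0.588). Among 27 DNA replication genes, 3 rose, the ribonucleotide reductase gene RRM2 (22.001 ± 0.219 to 28.4 ± 0.822), the cyclin gene CCNE1 (9.23 ± 0.156 to 11.6 ± 0.331) and the thymidylate synthase gene TYMS (13.3 ± 0.0469 to 15.2 ± 0.397), and MCM3 (139 ± 1.52 to 118 ± 0.200) fell. There 8 were higher and 1 lower adjusted over the list alone, and the median was 0.10 (camera adjusted p = 0.00149, adjusted p = 0.362 with an estimated correlation). DNA repair genes did not pass as a list (camera adjusted p = 0.315), with a median of 0.05 over 24 tested. Of these, 1 was higher and 0 lower over all genes, and 0 were higher and 0 lower adjusted over the list alone. That list was called as higher without the filter on low values (camera adjusted p = 0.0391). Replication-dependent histones (camera adjusted p = 0.321) had 2 risers of 6 tested, H2AC6 (2.60 ± 0.0977 to 4.08 ± 0.492) and H2BC12 (18.3 ± 1.26 to 22.9 ± 1.16), and 3 were higher and 0 lower adjusted over the list alone. TYMS and H2BC12 lost their calls whichever library was left out, and KIF20A, BUB1B and CCNE1 lost their calls without control 1, control 2 or drug 1. PLK1 and H2AC6 lost their calls without control 1, control 2 or drug 2, and NDC80 lost its call without control 1 or control 2. MCM3 lost its call without control 1. H2BC12 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0587). With edgeR on recovered reads TYMS and H2BC12 did not pass (adjusted p = 0.0827 and 0.105).

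Of 27 ribosome biogenesis and MYC target genes 8 rose and none fell, and 14 were higher and 0 lower adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.000268, adjusted p = 0.362 with an estimated correlation). FBL was the largest riser by far, and the next were the ornithine decarboxylase gene ODC1 (422 ± 7.09 to 530.3 ± 4.80), the spermidine synthase gene SRM (57.5 ± 0.777 to 66.7 ± 1.12) and BYSL (23.3 ± 0.939 to 27.03 ± 0.274), a small-subunit assembly factor. Without FBL the list kept its call, with 7 of 26 higher (camera adjusted p = 0.000857, chosen after the values were seen). Of 29 cytosolic ribosomal protein genes 10 fell and none rose, and 0 were higher and 24 lower adjusted over the list alone, with a median of -0.11 (camera adjusted p = 1.41e-10, adjusted p = 0.362 with an estimated correlation). Examples were RPL27 (297 ± 13.5 to 260.3 ± 4.45 FPKM) and RPL3 (322 ± 3.14 to 286 ± 0.348), RPS23 (48.04 ± 1.04 to 42.6 ± 0.170) and RPLP1 (291 ± 3.80 to 263 ± 2.17). The mean log2 fold change of this list was 0.03, opposite in sign to its median and test, because of RPS18, whose recovered reads were 9 and 3 in control and 23236 and 7 in drug libraries. Fry did not call this list (adjusted p = 0.0560). Ribosomal protein genes took 4.47% and 4.60% of reads in control and 4.29% and 4.21% in drug libraries. Proteasome subunits did not pass (camera adjusted p = 0.232), with PSMD1 (19.8 ± 0.0627 to 22.8 ± 0.354) and PSMC1 (19.3 ± 0.254 to 21.9 ± 0.588) higher of 19 tested, and 2 were higher and 0 lower adjusted over the list alone. They were called as higher without the filter on low values (camera adjusted p = 0.0391). SRM, BYSL, RPL27, RPL3, RPS23, RPLP1, PSMD1 and PSMC1 lost their calls whichever library was left out. BYSL and PSMC1 also lost their limma calls with TMM-scaled FPKM (adjusted p = 0.0556 and 0.0840).

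Of 9 biliary and progenitor genes 4 rose and none fell, LGR5, the surface glycoprotein gene CD24 (289 ± 2.45 to 394 ± 4.59 FPKM), the aminopeptidase gene ANPEP (81.4 ± 1.94 to 109 ± 2.15) and the transcription factor gene SOX4 (16.1 ± 0.183 to 19.05 ± 0.242). In this list 4 were higher and 0 lower adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0177, adjusted p = 0.508 with an estimated correlation), and the list lost its call without drug 2 (camera adjusted p = 0.0542). Of 11 Wnt targets, LGR5, the ubiquitin ligase genes ZNRF3 (5.58 ± 0.184 to 8.55 ± 0.116) and RNF43 (3.30 ± 0.114 to 4.08 ± 0.0818) and TBX3 (11.7 ± 0.274 to 15.6 ± 0.596) rose, and the cyclin gene CCND1 (43.2 ± 0.394 to 36.8 ± 0.473) fell. In the Wnt list 5 were higher and 1 lower adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0277, adjusted p = 0.362 with an estimated correlation), and its call was lost with edgeR on recovered reads (camera adjusted p = 0.0576). Of 6 xenobiotic metabolism genes 3 rose: CYP1A1, TIPARP (13.9 ± 0.544 to 23.8 ± 0.0601), another aryl hydrocarbon receptor target, and the efflux pump gene ABCG2 (10.3 ± 0.594 to 15.9 ± 0.595). The pump gene ABCB1 (8.14 ± 0.436 to 5.57 ± 0.340) fell. In the xenobiotic list 4 were higher and 1 lower adjusted over the list alone, with a median of 0.39 (camera adjusted p = 0.0200, adjusted p = 0.362 with an estimated correlation), and the list lost its call without the filter on low values (camera adjusted p = 0.353). SOX4, RNF43 and CCND1 lost their calls whichever library was left out, and ABCB1 lost its call without control 1, control 2 or drug 1. TBX3 lost its call without control 1. RNF43 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0634).

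Of 18 tubulin and cytoskeletal genes 10 rose and none fell, including the myosin light chain gene MYL9 (7.36 ± 0.785 to 13.01 ± 0.0586 FPKM), the filamin gene FLNA (31.9 ± 0.569 to 41.5 ± 2.16), the alpha-actinin gene ACTN1 (13.9 ± 0.258 to 18.04 ± 0.363) and the tropomyosin gene TPM2 (74.9 ± 1.45 to 94.7 ± 0.945). In this list 11 were higher and 0 lower adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.000422, adjusted p = 0.508 with an estimated correlation). Of 16 heat shock genes 9 rose and none fell, and 11 were higher and 0 lower adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.000422, adjusted p = 0.362 with an estimated correlation). Risers included HSP90AA1 (523 ± 2.71 to 655 ± 32.8), HSPA8 (467 ± 10.3 to 562 ± 6.17), the HSP90 co-chaperone gene AHSA1 (52.4 ± 2.09 to 63.1 ± 0.0345) and the collagen chaperone gene SERPINH1 (8.29 ± 0.452 to 10.5 ± 0.0660). Epithelial-mesenchymal transition genes did not pass as a list (camera adjusted p = 0.780). The list holds mesenchymal and epithelial genes together, so a test for a shared direction cannot decide whether such a transition took place. Of 12 tested, the mesenchymal genes VIM (5.02 ± 0.110 to 9.86 ± 0.371) and FN1 (126 ± 0.377 to 158 ± 3.42) rose with CTNNB1 (28.2 ± 0.674 to 33.6 ± 0.331) and TGFBI (40.3 ± 0.446 to 44.4 ± 0.164), while the epithelial cadherin gene CDH1 (12.4 ± 0.0189 to 7.80 ± 0.104) and SNAI1 (4.28 ± 0.118 to 3.31 ± 0.231) fell, and 5 were higher and 3 lower adjusted over the list alone. TGF-beta targets did not pass either (camera adjusted p = 0.156). Of 15 tested, ID1 (345 ± 8.29 to 210.2 ± 10.4), ID2 (137 ± 1.32 to 90.2 ± 3.21), ANGPTL4 and SMAD6 were among those that fell, and BMP4 (8.75 ± 0.0971 to 14.5 ± 0.0215), SKIL (19.6 ± 0.642 to 25.1 ± 0.816) and TGFBI rose, and 3 were higher and 6 lower adjusted over the list alone. YAP/TAZ targets did not pass (camera adjusted p = 0.525), with CCN1 (15.8 ± 1.05 to 26.2 ± 3.04), MYOF (15.1 ± 0.389 to 23.1 ± 0.138) and AJUBA (14.6 ± 0.372 to 17.4 ± 0.0724) higher of 14 tested, and 3 were higher and 0 lower adjusted over the list alone. SMAD6 lies outside the rule and was named after its values were seen. SERPINH1, TGFBI, SNAI1, SMAD6 and AJUBA lost their calls whichever library was left out, and AHSA1 and CTNNB1 lost their calls without control 1, drug 1 or drug 2. FLNA, HSP90AA1 and CCN1 lost their calls without control 1 or control 2, and SKIL lost its call without control 1 or drug 2. ACTN1, HSPA8 and ANGPTL4 lost their calls without control 1. TGFBI also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0923). With edgeR on recovered reads SNAI1 did not pass (adjusted p = 0.0551).

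Of 22 ATF4 and amino acid response genes 9 fell, among them the mTOR inhibitor gene DDIT4 (98.99 ± 1.17 to 55.6 ± 0.333 FPKM), STC2 (8.32 ± 0.769 to 4.46 ± 0.364), the serine synthesis gene PHGDH (6.09 ± 0.683 to 3.80 ± 0.102) and the cystine transporter gene SLC7A11 (4.92 ± 0.246 to 3.71 ± 0.243), and ATF5 (6.60 ± 0.513 to 8.38 ± 0.258) and NUPR1 (6.196 ± 0.0412 to 7.16 ± 0.159) rose. In this list 4 were higher and 11 lower adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.00208, adjusted p = 0.362 with an estimated correlation), and fry did not call it (adjusted p = 0.0551). Of 23 NRF2 targets 7 fell, including the aldo-keto reductase genes AKR1C2 (22.97 ± 0.128 to 16.9 ± 0.486) and AKR1C3 (6.88 ± 0.190 to 4.90 ± 0.195) and the ferritin light chain gene FTL (6077 ± 24.2 to 4909 ± 4.67), while the glutathione synthesis genes GCLC (16.9 ± 0.286 to 21.9 ± 0.0336) and GCLM (48.8 ± 0.356 to 57.4 ± 0.896) and TXNRD1 rose. Of the NRF2 targets 5 were higher and 12 lower adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.00699, adjusted p = 0.362 with an estimated correlation), and the list lost its call without the filter on low values (camera adjusted p = 0.0579). Of 16 ferroptosis and iron genes 6 fell, with the iron exporter gene SLC40A1 (27.9 ± 0.363 to 21.4 ± 0.395), the transferrin receptor gene TFRC (132 ± 1.17 to 102 ± 1.75) and ACSL4 (152 ± 1.85 to 119 ± 2.49) among them, and SAT1 (88.9 ± 0.0172 to 132 ± 1.98) and AIFM2 (6.62 ± 0.210 to 8.04 ± 0.0340) rose. In this list 4 were higher and 9 lower adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.00699, adjusted p = 0.362 with an estimated correlation). AKR1C2 and AKR1C3, and FTL with its pseudogenes, could share reads with near-identical copies. TXNRD1 lies outside the rule and was named after its values were seen. SLC7A11, ATF5, NUPR1, TXNRD1 and AIFM2 lost their calls whichever library was left out, and PHGDH lost its call without control 2, drug 1 or drug 2. GCLM lost its call without control 1, control 2 or drug 1, and AKR1C3 and FTL lost their calls without control 1 or control 2. NUPR1 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0629). With edgeR on recovered reads NUPR1 did not pass (adjusted p = 0.0558).

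Endoplasmic reticulum chaperone genes split evenly: HERPUD1 (28.4 ± 0.0722 to 20.4 ± 0.0860 FPKM), SDF2L1 (25.4 ± 1.08 to 21.5 ± 0.0720) and MANF (31.8 ± 0.772 to 27.1 ± 1.42) fell and DNAJB9 (34.4 ± 0.206 to 40.3 ± 0.0426), SEL1L (21.7 ± 0.613 to 24.4 ± 0.529) and DNAJC3 rose, of 21 tested. In this list 3 were higher and 5 lower adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.0313, adjusted p = 0.493 with an estimated correlation), and the list lost its call without control 2 (camera adjusted p = 0.0885), without drug 2 (0.147), without the filter on low values (0.0623), after correction for GC content, exon length and abundance (0.0917) and with fry (0.117). The p53 targets CDKN1A (4.41 ± 0.263 to 2.63 ± 0.254), PMAIP1 (12.6 ± 0.00631 to 9.68 ± 0.0385) and CCNG1 fell and TP53I3 (8.82 ± 0.486 to 12.4 ± 0.253) rose, of 20 tested, and 2 were higher and 3 lower adjusted over the list alone, with no list call (camera adjusted p = 0.800). Apoptosis regulators did not pass (camera adjusted p = 0.889): BID (4.26 ± 0.143 to 5.46 ± 0.241) and BMF rose, CASP9 (6.81 ± 0.412 to 4.57 ± 0.208) and PMAIP1 fell, of 21 tested, and 5 were higher and 3 lower adjusted over the list alone. Autophagy and lysosome genes did not pass (camera adjusted p = 0.168), with ULK1 (7.08 ± 0.280 to 8.58 ± 0.508) and ATP6V1H (9.33 ± 0.204 to 10.6 ± 0.0694) higher and RRAGD (4.61 ± 0.269 to 3.55 ± 0.0992) and GLB1 (18.4 ± 0.162 to 16.5 ± 0.318) lower of 25 tested, and 2 were higher and 3 lower adjusted over the list alone. Zinc and copper stress genes, mostly transporters, did not pass (camera adjusted p = 0.321), with the ferredoxin gene FDX1 (22.6 ± 0.297 to 18.2 ± 0.161) and the transporter genes SLC30A10 (3.44 ± 0.156 to 2.54 ± 0.165) and SLC31A1 (28.2 ± 0.461 to 25.3 ± 0.344) lower of 10 tested, and 1 was higher and 3 lower adjusted over the list alone. Their median was 0.01, while their mean was -0.04 and the test pointed down. Of 6 listed genes of the metallothionein list, 5 metallothioneins and the zinc transporter gene SLC30A1, 2 were tested and none passed, with MT2A, the 1 metallothionein tested, at 2.61 and 3.09 FPKM in control and 3.20 and 2.66 FPKM in drug libraries; adjusted over the list alone 1 was higher, SLC30A1. DNAJC3, CCNG1 and BMF lie outside the rule and were named after their values were seen. SDF2L1, MANF, DNAJB9, SEL1L, DNAJC3, CCNG1, BID, ULK1, ATP6V1H, RRAGD, GLB1, SLC30A10 and SLC31A1 lost their calls whichever library was left out, and CDKN1A lost its call without control 1 or control 2. CASP9 lost its call without control 2 or drug 1, and PMAIP1 and FDX1 lost their calls without control 1. SEL1L, DNAJC3, ULK1 and ATP6V1H also lost their limma calls with TMM-scaled FPKM (adjusted p = 0.113, 0.0653, 0.0574 and 0.0780). With edgeR on recovered reads ATP6V1H did not pass (adjusted p = 0.0525).

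Of 16 NF-kappaB and inflammatory genes tested, 4 fell, all chemokine genes, and 2 rose. CCL20 (184 ± 1.11 to 88.6 ± 3.42 FPKM), which attracts CCR6-bearing lymphocytes, fell furthest, and the neutrophil chemokine genes CXCL1 (37.6 ± 2.15 to 30.7 ± 1.15), CXCL3 (2.88 ± 0.0996 to 1.93 ± 0.200) and CXCL8 (45.6 ± 1.98 to 37.8 ± 1.26) fell too, while CSF1 (2.38 ± 0.239 to 3.61 ± 0.130) and the NF-kappaB subunit gene RELB (8.52 ± 0.144 to 10.4 ± 0.475) rose. In this list 2 were higher and 4 lower adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0163, adjusted p = 0.586 with an estimated correlation), and the call was lost without drug 1 (camera adjusted p = 0.0773) and with fry (0.184). CXCL1 and CXCL3 are similar copies that could share reads. Of 12 senescence-associated secretion genes 6 fell, among them CCL20 and IGFBP3 (13.9 ± 0.421 to 10.5 ± 0.0303), and LMNB1 (26.7 ± 0.470 to 29.9 ± 0.849) and AREG (41.1 ± 0.528 to 45.7 ± 0.528) rose. LMNB1 encodes a nuclear lamin and not a secreted protein. In this list 2 were higher and 6 lower adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.000917, adjusted p = 0.362 with an estimated correlation). Interferon-stimulated genes, with 1 of 13 tested higher and 0 lower, also when adjusted over the list alone, did not pass (camera adjusted p = 0.0597, median -0.10). They were called as lower without control 1 (camera adjusted p = 0.0487). Antigen presentation genes had 3 of 14 listed members tested and none passed, and none passed when adjusted over the list alone. The 64 listed coding genes of the major histocompatibility region of chromosome 6 had a median of 0.0293 FPKM, against 2.83 FPKM for 15270 elsewhere. Most genes of this list in that region were below the filter, so the list cannot show whether antigen presentation changed. B2M was at 21.8 and 23.2 FPKM in control and 24.0 and 24.1 FPKM in drug libraries. CXCL1, CXCL3, CXCL8, CSF1, RELB, LMNB1 and AREG lost their calls whichever library was left out. LMNB1 and AREG also lost their limma calls with TMM-scaled FPKM (adjusted p = 0.118 and 0.0634). With edgeR on recovered reads AREG did not pass (adjusted p = 0.0539).

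Immediate early and ERK output genes went both ways and did not pass as a list (camera adjusted p = 0.139). FOS (30.7 ± 3.13 to 20.4 ± 0.386 FPKM), DUSP6 (14.9 ± 0.216 to 11.9 ± 0.151), ETV4 (26.2 ± 0.839 to 21.4 ± 1.27), JUNB (33.9 ± 1.30 to 29.7 ± 0.917) and CCND1 were among the 6 of 20 that fell, and JUN (30.1 ± 0.570 to 43.6 ± 1.66), FOSL1 (2.57 ± 0.269 to 3.96 ± 0.170) and DUSP1 (72.9 ± 2.06 to 82.2 ± 1.94) rose, and 4 were higher and 7 lower adjusted over the list alone. Glucocorticoid receptor targets did not pass (camera adjusted p = 0.780), with FKBP5 (12.2 ± 0.106 to 15.5 ± 0.441) and DUSP1 higher and ANGPTL4 lower of 10 tested, and 3 were higher and 2 lower adjusted over the list alone. Their median was 0.03, while their mean was -0.03 and the test pointed down. Genes responsive to BET and CDK9 inhibitors did not pass (camera adjusted p = 0.479), with FOSL1 higher and JUNB and CCND1 lower of 10 tested, and 2 were higher and 2 lower adjusted over the list alone. Of 14 circadian clock genes BHLHE40 (26.98 ± 0.226 to 17.8 ± 1.0025) and NFIL3 (32.9 ± 0.198 to 27.4 ± 0.900) fell and HLF (9.03 ± 0.0427 to 10.4 ± 0.0171) rose, and 1 was higher and 2 lower adjusted over the list alone, with no list call (camera adjusted p = 0.494). JUNB, CCND1, FOSL1, DUSP1 and HLF lost their calls whichever library was left out, and DUSP6 and NFIL3 lost their calls without control 1, control 2 or drug 2. ETV4 lost its call without control 1, control 2 or drug 1, and FOS lost its call without drug 1 or drug 2. FKBP5 lost its call without control 1 or control 2. DUSP1 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0597).

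Of 13 genes of the mitochondrial genome only the cytochrome oxidase gene MT-CO3 (13207 ± 362 to 11329 ± 493 FPKM) fell, and none passed when adjusted over the list alone. The list had a median of -0.03 (camera adjusted p = 0.0453, adjusted p = 0.677 with an estimated correlation). That call was kept in 9 of 15 other settings. It ended without control 1 (camera adjusted p = 0.412) and without drug 2 (0.772), with medians of 0.02 and 0.03, without the filter on low values (0.426), with TMM-scaled FPKM (0.0739) and with fry (0.601). It turned to higher after correction for GC content, exon length and abundance (median 0.10, camera adjusted p = 0.00537). Mitochondrial genome genes took 10.8% and 10.5% of reads in control and 10.3% and 9.61% in drug libraries. Nuclear oxidative phosphorylation genes did not pass (camera adjusted p = 0.156). Of 22 tested, 1 was higher and 0 lower, and none passed when adjusted over the list alone. Their median was -0.00, their mean was 0.05 and the test pointed down, with a call as lower without control 1 (camera adjusted p = 0.0233, median -0.04). MT-CO3 lost its call whichever library was left out. MT-CO3 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0723).

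Markers of other cell types were mostly below the filter. None of 12 listed fibroblast and stellate markers passed the filter, and TAGLN was at a mean of 0.492 FPKM in control and 0.469 FPKM in drug libraries. Of 8 listed endothelial markers 1 was tested: PECAM1 fell, from 4.66 and 4.11 FPKM in control to 2.09 and 2.23 FPKM in drug libraries (limma adjusted p = 0.00669). Of 9 listed leukocyte markers 1 was tested: the lysozyme gene LYZ rose, from 181 and 183 FPKM to 283 and 287 FPKM (limma adjusted p = 0.000841). Adjusted over the list alone the counts were 1 lower and 1 higher, which says no more, since with 1 tested member that is the unadjusted p. The leukocyte genes CD2 and CD14 were at means of 0.0587 and 0.140 FPKM in control and 0.0234 and 0.0935 FPKM in drug libraries. PECAM1 and LYZ lie outside the rule and were named after their values were seen.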

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

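The fits with TMM-scaled FPKM, recovered reads, a minimum fold, the GC and length correction, discordant genes removed and the list without FBL were chosen after the data were seen; the others were planned. No gene called by limma was called in the opposite direction in any of these settings. Of 205 named genes, 205 kept their side of the threshold with pseudocounts of 0.1 and of 0.01, 191 after correction for GC content, exon length and abundance, 194 with edgeR and 182 with TMM-scaled FPKM. With the replicate block 157 kept it and 48 lost their call, and without the filter on low values 96 kept it and 109 lost their call.

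Against 873 higher and 676 lower genes, no filter on low values gave 170 and 214, where more genes were tested. Leaving out 1 library gave 115 to 221 higher and 188 to 274 lower, with fewer samples. Without the 87 genes discordant between replicates, 970 were higher and 717 lower. TMM-scaled FPKM gave 554 higher and 779 lower. On recovered reads, edgeR gave 1277 and 1503 with TMM, 1259 and 1498 with median-of-ratios factors, and 1945 and 1213 without a composition factor. It gave 1412 and 1504 without a low-count filter, and 1337 and 1589 with a filter of 1 CPM in 2 libraries and a mean of 2 CPM. DESeq2 gave 1042 and 1222, and limma-voom 961 and 1214. For the scaling and tool differences the cause was not tested. Against a fold of at least 1.5, a stricter hypothesis, limma treat gave 7 and 15 and edgeR glmTreat 34 and 79.

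With the replicate block, limma gave 474 higher and 451 lower genes, and edgeR 1290 and 1510. Libraries of the same number deviated from their group means with a correlation of 0.0278, so the numbers were not taken to pair the samples. No list call changed under the block, while 48 of the 205 named genes lost theirs in limma.

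Of 42 lists, camera with an estimated correlation called 0 as higher and 0 as lower. Of the 25 called lists, 14 kept their call in all 15 other settings. The mitochondrial genome list reversed to a median of 0.10 after correction for GC content, exon length and abundance (camera adjusted p = 0.00537). Of the lists that did not pass, 4 gained a call: DNA repair and proteasome subunits as higher without the filter on low values (camera adjusted p = 0.0391 each), and nuclear oxidative phosphorylation (0.0233) and interferon-stimulated genes (0.0487) as lower without control 1. The p53 targets reversed in test direction without control 2 (medians of 0.0515 to 0.0634 with each library left out; camera adjusted p = 0.991). The glucocorticoid receptor targets reversed in test direction with fry (median 0.0304, adjusted p = 0.816). In each case the cause was not tested. Lists on recovered reads were not run with other low-count filters or with the block. Depth limits genes under 1 FPKM, which were not tested with limma.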

Other observations

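The amino acid and collagen lists, the apolipoprotein list and the tests of library scaling and of genes discordant between replicates were chosen after the result was seen; the other tests of the 4-list pattern and that of aryl hydrocarbon receptor targets were written before their results, after CYP1A1 and TIPARP had been seen.

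Of 37 tested genes of amino acid breakdown, 15 fell and 1, FAH, rose, with a median log2 fold change of -0.25 (camera adjusted p = 1.10e-10, adjusted p = 0.0491 with an estimated correlation). Adjusted p-values of this, the apolipoprotein and the collagen list are over these 3 lists alone. Those of the fixed lists are over 42, so the 2 sets cannot be compared. Besides HAL and SDS, AMDHD1 (25.1 ± 0.0602 to 11.6 ± 0.244 FPKM), a later step of histidine breakdown, fell, as did the urea cycle gene ASS1 (456 ± 14.97 to 323 ± 0.655), the tyrosine breakdown genes HPD (21.8 ± 0.197 to 15.3 ± 0.613) and HGD (69.3 ± 2.47 to 53.8 ± 1.30), the ornithine aminotransferase gene OAT (148 ± 2.31 to 114 ± 3.52) and CTH (15.9 ± 0.300 to 10.6 ± 0.459). Without the 4 genes already seen, HAL, SDS and AMDHD1 among them, 11 of 33 fell and 1 rose, with a median of -0.14 (unadjusted camera p = 9.20e-08, and unadjusted p = 0.0255 with an estimated correlation). FAH lost its call whichever library was left out and with TMM-scaled FPKM (limma adjusted p = 0.0705), and the list remains a pattern found in these data.

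Apolipoprotein genes moved apart: APOC1 (46.8 ± 1.1988 to 76.3 ± 0.422 FPKM) and APOA2 rose and APOA1, APOH and APOC3 fell, of 7 tested (camera adjusted p = 0.858). Their median and mean were both 0.03 while the test, which is relative to the other tested genes, pointed down. Of 15 collagen-modifying genes LOXL4 and SERPINH1 rose and LOX, PLOD2 (3.71 ± 0.339 to 2.47 ± 0.0928), P4HA1 (36.4 ± 1.37 to 29.8 ± 1.14) and CRTAP (21.8 ± 0.281 to 18.5 ± 0.293) fell (camera adjusted p = 0.289). APOA1, APOC3, PLOD2, P4HA1 and CRTAP lost their calls whichever library was left out, and APOA2 and APOH lost their calls without control 1, control 2 or drug 1. APOA2 also lost its limma call with TMM-scaled FPKM (adjusted p = 0.0503). With edgeR on recovered reads APOC3 did not pass (adjusted p = 0.0616).

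Mitotic genes were higher and glycolysis, hypoxia and ribosomal protein genes lower with drug by camera with its preset correlation (adjusted p = 0.362 for each of the 4 lists with an estimated correlation, and 0.0560 for ribosomal proteins with fry). All 4 lists kept direction and a camera adjusted p under 0.05 after correction for GC content, exon length and abundance, while their calls with TMM-scaled FPKM decide nothing, since TMM moves the genes of a library nearly alike. A scaling by total reads would move all lists the same way, so it alone cannot give opposite directions. The gap between the lists restates the pattern already seen and is no separate evidence. With each library left out the mitosis median lay at least 0.325 above the highest of the other 3, and 0 of 16 medians changed sign: 0.20 to 0.23 for mitosis, -0.28 to -0.18 for glycolysis, -0.36 to -0.25 for hypoxia and -0.13 to -0.09 for ribosomal proteins. The calls kept after correction argue against GC content, exon length and abundance as the whole cause, and the unchanged signs argue against a single library. For scaling, the opposite directions are the pattern itself, and the gap adds nothing to them. A difference in culture density, medium or batch between the groups is not labelled and stays open beside an effect of the drug.

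CYP1A1 and TIPARP rose, and a candidate explanation is aryl hydrocarbon receptor activity. Of 12 other targets written down before the test, 5 were tested, with a median log2 fold change of 0.0875 and 1 higher, HES1 (limma adjusted p = 0.0354, edgeR adjusted p = 0.0680). CYP1B1, below the filter, had 12 and 22 reads in control and 79 and 93 in drug libraries (edgeR log2 fold change 2.08, adjusted p = 2.86e-05), while AHRR had 13 and 4 against 8 and 7 reads. These values leave the explanation open, since 5 genes with small changes are too few to decide.

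Some genes had many reads in 1 library and almost none in its replicate, as RPS18 did. In the major histocompatibility region of chromosome 6, which has alternate copies in hg38, 4 of 17 genes differed over 4-fold between replicates after the 3 already seen were left out, against 80 of 11909 elsewhere (odds ratio 45.4, Fisher's exact two-sided p = 5.08e-06). Outside it, 38 of 80 such genes lay within 500 kb of another, against a median of 4 and at most 15 in 1000 draws matched on gene density, and counting error alone, with mate pairs counted once, would put 2.27 of all 11929 genes over 4-fold against the 87 seen, which argues against sampling noise. Reads may have been placed on alternate copies of these sequences, an alignment step not given in the sources used here, and 2 earlier noise tests decided nothing: 1 found 1 gene over 1000 reads in 1 replicate and under 50 in the other, against a bound of 3, and 1 used only genes chosen for their difference. Of the 87 genes 0 were called by limma, but they were chosen for a spread between replicates that works against a call. That count therefore says nothing about called genes affected alike in both libraries of a group. FBL had 0 of the discordant genes within 500 kb and GMPR2 had 3. The discordant gene LRFN1, on chromosome 19 at 39306568 to 39315336, lies only slightly outside that window of FBL. Whether FBL or GMPR2 was affected in both libraries of a group was not tested.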
